A study of Mus musculus with 8 samples.

How the data were processed

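RNA of sorted CD4-negative CD8-negative cells was amplified and hybridised to Affymetrix mouse arrays, per the labels' protocols, with 8 arrays in 4 groups of 2. The authors deposited log2 values for 22690 probe sets, and RMA is the tool named in the submitters' processing notes, with no version. The deposited values ran from 2.54 to 13.9 with array medians between 4.81 and 4.91. RMA corrects background, makes the value distributions of the arrays alike and fits a summary over the probes of a set, so a shift common to most genes of an array would not be seen, and differences of dim probe sets are compressed. Signal over background per probe was not used here.

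Groups were taken from the sample titles. The Treatment field of the emigrant array titled oil 1 names TCDD, that of emigrants oil 2 reads Dioxane 2, and the Tissue field of some emigrant arrays reads thymus. Following the Treatment field for emigrants oil 1 was tried as an alternative. The protocol gives the dose as 10 µg/kg and the Treatment field as 10 nM.

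Probe sets were named from the platform annotation, with symbols updated through the gene identifier from a RefSeq gene table of the GRCm38.p6 assembly used for names only. Of the probe sets, 20393 had 1 gene symbol, 691 several and 1606 none, and the last 2 kinds were left out. The symbols of 20364 probe sets were found through the identifier. Each gene was represented by its probe set with the highest mean over the 8 arrays, giving 12394 genes, of which 4958 had more than 1 probe set. No filter on dim genes was used. Of the 198 gene differences followed in the text, 94 belong to genes with several probe sets, and for 63 of these some other probe set had a difference of the opposite sign or over 3 times smaller. For 27 that other probe set had a mean level above the median of the arrays, and the text gives its difference beside the gene. In 30 cases both arrays of some group lay below their array medians, and no fold is given there since no level was shown to be above background.

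Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means, all 8 arrays, 4 residual degrees of freedom, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The median residual SD was 0.223 on the log2 scale. Of 30 gene lists, 29 had at least 5 measured members and were tested with camera at a preset correlation of 0.01 and, beside it, an estimated correlation. With an estimated correlation camera also uses the 4 residual degrees of freedom, so a larger p is not due to correlation alone. For the AhR targets in thymocytes the estimated correlation was -0.031, below the preset, and the camera p still went from 2.69e-05 to 0.0116. The list of the AhR complex had 4 measured members and was not tested. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes up to 10 genes higher and 10 lower among those past the threshold with no overlap between the arrays compared. Where fewer than 5 pass in a direction, the 5 with the smallest p are named with their values. It adds the AhR target genes, up to 4 members of each other list with the smallest p, and S100a8, S100a9, Cd4, Cd8a, Cd44, Il2ra, Il7r, Ccr9, Cd24a and Ptprc. Predicted genes with no name were skipped in naming. From the genes of this rule, the text prints the first 3 members by p of each list past the threshold, the AhR target genes where TCDD is compared and the fixed genes where they bear on the comparison. This narrowing was made after the data were examined.

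The code was tested on simulated arrays with the spread of the real ones, for the TCDD comparison in thymocytes over 12394 genes. It recovered 29.9% of genes changed by 1 log2 unit, 65.7% of those changed by 2 and 97.0% of those changed by 4, with 7 unchanged genes called. Of 20 lists raised by 0.5 log2 units, camera called 20 with the preset and 18 with an estimated correlation, and it called 0 of 20 unchanged lists. The simulated genes and arrays varied independently. In the real data the granulocyte list had an estimated correlation of 0.665 and the cell cycle list of 0.515, and same-numbered arrays deviated together within each source. The simulation therefore cannot tell how often camera calls an unchanged list of correlated genes, or what limma recovers from such arrays.

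Alternatives were a repeated quantile normalization, centring each array on its median, testing only the brighter genes (mean level above the median of all genes), testing every probe set, averaging the probe sets of a gene, an eBayes prior with trend and robust settings, the replicate number as a block, only the 4 arrays compared, the Treatment field in place of the title, and leaving out each array in turn. A fit without an array leaves 1 array in its group, which is then assumed to vary like the arrays of the other groups. The replicate number as a block within each cell source was added after the data were examined. Figures were drawn with matplotlib 3.10.9.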

Results

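The series profiled CD4-negative CD8-negative mouse cells from 2 places, the thymus (thymocytes) and the spleen (thymus emigrants), by Affymetrix expression array. Female C57BL/6 mice aged 6 to 8 weeks received either corn oil or the dioxin TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin), a ligand of the aryl hydrocarbon receptor (AhR), at 10 µg/kg by intraperitoneal injection. FITC was injected 5 days later to mark thymus cells, and the cells were sorted 24 h after that. Each of the 4 groups (thymocytes or emigrants, oil or TCDD) held 2 arrays, so the number of arrays limited the precision of each value. The labels do not say whether the 2 arrays of a group came from separate mice or pools, so p-values measure only the spread between these samples, which may be technical. The emigrant array titled oil 1 carries a Treatment field that names TCDD, and the groups used here follow the titles. The same field gives a TCDD concentration of 10 nM, which is not the injected dose.

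The first principal component of the 12394 genes, with 41.3% of the variance, placed all 4 thymocyte arrays above all 4 emigrant arrays. Spearman's rho across genes was 0.986 and 0.987 between the oil and TCDD thymocyte arrays numbered 1 and 2, and 0.959 and 0.968 between the 2 arrays of the oil and of the TCDD thymocytes. In the emigrants it was 0.988 between oil 1 and TCDD 1, 0.970 between oil 2 and TCDD 2, 0.967 between the oil arrays and 0.952 between the TCDD arrays, while emigrants oil 2 and thymocytes TCDD 2 had a rho of 0.973. Emigrants TCDD 2 stood apart on the second component, at -34, with the other arrays at -14.2 or above. Genes are not independent replicates in these correlations. Leaving out 1 array moved 80 of the 198 gene differences followed here by over 1.5 times or turned their sign.

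The first comparison asked which genes respond to TCDD in the thymocytes. Cyp1b1, a cytochrome P450 and known AhR target, was 18.3-fold higher after TCDD (SE 0.705 on the log2 scale, n = 2 against 2). It lay at 4.62 and 5.04 in the oil arrays, close to their medians of 4.81 and 4.85. The size of this fold thus depends on levels not shown to be above background. Scin, which encodes the actin-severing protein scinderin, was 9.75-fold higher. Tiparp, an ADP-ribosyltransferase, was 2.82-fold higher, and had another probe set, at a mean level of 5.04, with a log2 difference of 0.24. Nqo1, a quinone reductase, and Ahrr, the AhR repressor, had log2 differences of 0.47 and 0.68, with both oil arrays below the array medians. Both TCDD arrays lay above both oil arrays for 6 of the 11 measured AhR target genes. The list passed the camera test in the upward direction (median log2 difference 0.08, mean 0.89, camera adjusted p = 0.000195, or 0.268 with an estimated correlation). Of its members 8 had a higher and 3 a lower mean under TCDD. The large differences of Cyp1b1, Scin and Tiparp set the mean above the median, so the call does not show a rise of the list as a group. The differences were small for Cyp1a1 (-0.11), Cyp1a2 (0.06), Aldh3a1 (0.05), Selenbp1 (0.08), Nfe2l2 (-0.09) and Xdh (-0.33). Without thymocytes TCDD 2 the log2 difference of Tiparp was 0.92, and without thymocytes oil 1 that of Nqo1 was 0.25. Without thymocytes oil 2 that of Ahrr was 0.43, and Aldh3a1, Cyp1a1, Selenbp1 and Nfe2l2 turned their sign with some array left out. The list median was 0.18 without thymocytes oil 1 and 0.33 without thymocytes TCDD 2.

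Outside that list, the genes with the smallest p among those higher in TCDD thymocytes were Mpzl2, an adhesion molecule of the immunoglobulin superfamily (4.13-fold), Itgae, the integrin chain CD103 (4.51-fold), Agfg1 (log2 difference 1.32) and Tab3 (0.92). Among those lower were Parvg (log2 difference -0.97), Adssl1 (-0.74), Ipo9 (-0.77), Tpst1 (-0.53) and Ccnd3 (-0.71), which encodes cyclin D3. Another Parvg probe set, at a mean level of 5.14, had a difference of -0.08. The glycolysis list fell (median -0.36, camera adjusted p = 2.35e-05; adjusted p = 0.49 with an estimated correlation), with Pfkp at -0.46, Pkm at -0.69 and Pgam1 at -0.55. The cell cycle list fell as well (median -0.34, camera adjusted p = 4.33e-06; adjusted p = 0.774 with an estimated correlation), with Mcm5 at -1.12, Mcm2 at -0.47 and Aurkb at -0.71. The interferon response list rose (median 0.35, camera adjusted p = 8.55e-06; adjusted p = 0.268 with an estimated correlation), with Rsad2 at 0.94 (0.28 for another probe set, at a mean level of 7.11), Mx1 at 0.45 and Ifit3 at 0.33. The cell cycle and interferon calls ended when some single array was left out. Leaving out 1 array also leaves its same-numbered partner unmatched, although these arrays deviated together (r of 0.76), so such values mix TCDD with the replicate number. The members named above, those with the smallest p, moved in the same direction within both numbers, as in Mcm5 (7.42 to 6.47 and 7.57 to 6.29) and Rsad2 (8.21 to 9.36 and 8.75 to 9.47). They were picked by p in this same comparison, so this agreement is not separate support for the calls. Other interferon members did not all move so, as in Gbp2 (6.56 to 7.07 and 6.55 to 6.49) and Igtp (6.94 to 7.65 and 7.90 to 7.89). Without thymocytes oil 1 the cell cycle median was -0.04 (adjusted p = 0.525) and the interferon median 0.22 (adjusted p = 0.146), and without thymocytes TCDD 2 they were -0.16 (adjusted p = 0.358) and 0.17 (adjusted p = 0.133). Without thymocytes oil 2 the medians were -0.69 and 0.62, and the cell cycle median was -0.69 without thymocytes TCDD 1.

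No single gene passed the limma test over all 12394 genes in the thymocytes (0 genes, smallest adjusted p = 1). At an unadjusted p under 0.05 there were 194 genes, 116 higher and 78 lower, where chance alone gives 620 for independent arrays. That number was 322 without thymocytes oil 1 and 386 without thymocytes oil 2. The arrays of the groups did not overlap for 21.2% of genes, against 33.3% by chance for independent arrays. Adjusted over the list alone, 1 AhR target gene passed, Cyp1b1 (adjusted p = 0.00908), and Itgae passed within the adhesion list (adjusted p = 0.0206), which did not pass as a list (camera adjusted p = 0.174). Members passed in this way in only 2 of the 29 lists. This adjustment does not count the number of lists searched, so some such passes would arise by chance. Of the 3 probe sets of Cyp1b1, the brightest carried its difference and the other 2, at mean log2 levels of 3.40 and 4.96, had differences of 0.69 and -0.08. The fit by group means behind these counts leaves the deviation shared by same-numbered arrays in the residual spread. In a fit chosen after the data were examined, with a replicate block within each source, 790 genes had an unadjusted limma p under 0.05. In that fit Cyp1b1 passed over all genes (limma adjusted p = 0.0156).

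**Figure D1:**
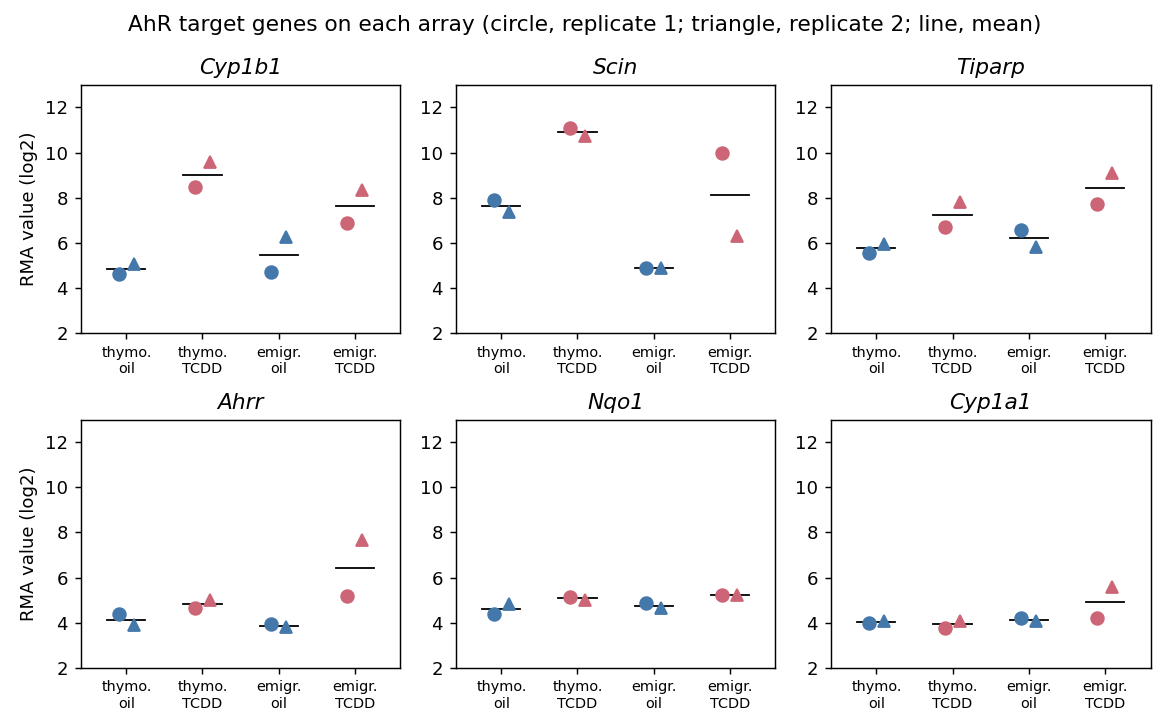
RMA log2 values of 6 AhR target genes on each of the 8 arrays, by cell source and treatment, with circles for replicate 1, triangles for replicate 2 and lines for the means. Cyp1b1 lay at 8.46 and 9.59 in TCDD thymocytes against 4.62 and 5.04 in oil thymocytes.

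In the emigrants, the same question of TCDD response was asked of cells that had left the thymus. Scin was 9.60-fold higher after TCDD (log2 difference 3.26, SE 1.05, n = 2 against 2), Tiparp 4.64-fold and Cyp1b1 4.42-fold, while another Cyp1b1 probe set, at a mean level of 4.96, had a log2 difference of 0.19. The log2 differences were 2.55 for Ahrr, 0.48 for Nqo1, 0.76 for Cyp1a1, the classical AhR-induced cytochrome P450, and 0.60 for Selenbp1. Both oil arrays lay below the array medians for Ahrr, Nqo1 and Cyp1a1, so the size of these differences depends on levels not shown to be above background. The same holds for the fold of Scin, which lay at 4.88 and 4.87 in the oil arrays, close to their medians of 4.89 and 4.85. All 11 measured AhR target genes had a higher mean under TCDD, among them Cyp1a2 (0.17), Aldh3a1 (0.10), Nfe2l2 (0.13) and Xdh (0.23), and both TCDD arrays lay above both oil arrays for 7 of them. The list rose (median 0.60, camera adjusted p = 1.71e-08; adjusted p = 0.0838 with an estimated correlation). The rise was uneven between the TCDD arrays, with Scin at 9.97 and 6.30 and Ahrr at 5.19 and 7.65 in replicates 1 and 2. Cyp1a1 was at 5.59 in TCDD 2, but at 4.22 in TCDD 1, near its levels in oil, and its difference without emigrants TCDD 2 was 0.08. Scin had a difference of 1.43 without emigrants TCDD 1, Ahrr of 1.32 without emigrants TCDD 2, Cyp1b1 of 1.37 without emigrants oil 1 and Selenbp1 of 0.23 without emigrants TCDD 1. The signs of Aldh3a1, Nfe2l2 and Xdh turned with some array left out. The list median was 0.92 without emigrants oil 1 and 0.36 without emigrants oil 2, and the call held in both cases.

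Eomes, a T-box factor of cytotoxic lymphocytes, had the largest difference among the lower genes with the smallest p (log2 difference -2.26), which also held Ptbp2 (2.01-fold lower), Mtrex (-0.91), Vbp1 (-0.85) and Gpm6b (-0.83). On the higher side were Gstm1 (1.00), St8sia1 (0.74), Kdelr1 (0.69) and Fam122a (0.58). Other probe sets, at mean levels of 4.93, 4.92 and 5.29, had differences of -0.42 for Eomes, 0.01 for Ptbp2 and 0.19 for Gstm1. Besides the AhR targets, 4 lists rose and 4 fell in the emigrants, and each of these 8 calls ended when some single array was left out. Same-numbered oil and TCDD emigrant arrays deviated together (r of 0.50). Leaving out 1 emigrant array therefore mixes TCDD with the replicate number, and a lost call does not show that the difference rests on that array. Beside these lists, the 3 prime minus 5 prime signal of actin was higher under TCDD within each replicate number (4.68 against 3.92 and 3.79 against 3.34), as was that of Gapdh (4.97 against 4.81 and 5.32 against 4.91). The granulocyte list rose (median 0.75, camera adjusted p = 0.000433; adjusted p = 0.549 with an estimated correlation), with Elane at 0.62, Prtn3 at 1.01 and Cd177 at 0.75. Without emigrants TCDD 1 its median was -0.17 (adjusted p = 0.301), and without emigrants TCDD 2 it was 1.92. Without emigrants TCDD 1 Prtn3 had a difference of 0.10 and Cd177 of 0.26. S100a8, at 10.61 and 5.56 in the TCDD arrays and 8.58 and 7.29 in the oil arrays, differed by 0.15, and S100a9 by 0.45. The erythroid list rose (median 0.50, camera adjusted p = 0.00737; adjusted p = 0.518 with an estimated correlation), with Klf1 at 0.53, Epor at 0.41 and Car2 at 1.11, and its median was -0.13 without emigrants TCDD 1 (adjusted p = 0.843), 0.08 without emigrants oil 2 (adjusted p = 0.611), 1.17 without emigrants TCDD 2 and 0.82 without emigrants oil 1. Car2 had a difference of 0.18 without emigrants oil 2 and 2.03 without emigrants oil 1. From oil to TCDD it went from 9.58 to 10.43 in number 1 and from 7.73 to 9.10 in number 2. Rhag, of the same list, went from 4.70 to 5.84 but from 3.29 to 3.12. The platelet list rose (median 0.18, camera adjusted p = 0.00524; adjusted p = 0.429 with an estimated correlation), with Pf4 at 1.99, Gp1bb at 0.36 and Gp5 at 0.26, and its median was 0.18 without emigrants oil 2 (adjusted p = 0.0776), 0.32 without emigrants TCDD 1 (adjusted p = 0.055) and 0.21 without emigrants TCDD 2 (adjusted p = 0.0599), no smaller than with all arrays. Without emigrants TCDD 2 the difference was 1.04 for Pf4 and 0.38 for Klf4. Immediate early genes rose (median 0.34, camera adjusted p = 0.00316; adjusted p = 0.518 with an estimated correlation), with Ier3 at 0.85, Btg2 at 0.52 and Klf4 at 0.83, and their median was 0.27 without emigrants oil 1 (adjusted p = 0.12) and 0.20 without emigrants TCDD 2 (adjusted p = 0.223). With emigrants oil 1 counted as TCDD, as its Treatment field has it, the median was 0.26 for the platelet list (adjusted p = 0.121) and 0.10 for the immediate early list (adjusted p = 0.568).

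Of the lists that fell in the emigrants, 3 hold genes of T cells and their development and 1 holds NK cell markers. The T cell receptor list fell (median -0.37, camera adjusted p = 0.00521; adjusted p = 0.518 with an estimated correlation), with Cd247 at -0.38 and Cd3g at -0.48, while its member Zap70 differed by 0.31. The pre-TCR and V(D)J recombination list fell (median -0.28, camera adjusted p = 0.00717; adjusted p = 0.515 with an estimated correlation), with Ptcra at -1.01, Tcf12 at -1.16 (-0.08 for another probe set, at a mean level of 6.22) and Rag1 at -2.42. The list of T lineage transcription factors fell (median -0.33, camera adjusted p = 0.0463; adjusted p = 0.515 with an estimated correlation), with Tox at -0.33, Myb at -2.03 and Gfi1 at -0.67. The list of NK cell markers fell (median -0.10, camera adjusted p = 0.00521; adjusted p = 0.515 with an estimated correlation), with Klrd1 at -1.33 and Tbx21 at -0.55. Without emigrants TCDD 2 the adjusted p was 0.955 for the first 3 of these lists and 0.13 for the NK list. Without emigrants oil 1 it was 0.651 for the T cell receptor list, 0.564 for the transcription factors and 0.0771 for the NK list, and without emigrants oil 2 it was 0.463 for the pre-TCR list. The pre-TCR median was -0.05 without emigrants oil 2, -0.12 without emigrants TCDD 2 with the test in the other direction, -0.43 without emigrants oil 1 and -0.45 without emigrants TCDD 1. The NK median was -0.39 without emigrants oil 2, -0.11 without emigrants oil 1, -0.46 without emigrants TCDD 1 and -0.17 without emigrants TCDD 2. The T cell receptor median was 0.02 without emigrants oil 1 and -0.04 without emigrants TCDD 2, and that of the transcription factors -0.01 and 0.08. For the transcription factors the p crossed the threshold at a median of the same size or larger in 5 further settings: -0.33 without thymocytes oil 1 and without thymocytes oil 2 (adjusted p = 0.0693 in both), -0.35 after a repeated quantile normalization (adjusted p = 0.081), -0.37 with arrays centred on the median (adjusted p = 0.0796) and -0.33 with only the 4 arrays compared (adjusted p = 0.0893). Among the brighter genes by mean level alone the medians were as large or larger too, at -1.01 for the pre-TCR list (adjusted p = 0.0842), -0.37 for the T cell receptor list and -0.39 for the transcription factors (adjusted p = 0.0587 for both). With the Treatment field of emigrants oil 1, the median turned to 0.01 for the NK list (adjusted p = 0.412), 0.19 for the T cell receptor list (adjusted p = 0.568) and 0.11 for the transcription factors (adjusted p = 0.939). Without emigrants TCDD 2 the difference of Klrd1 was -0.43, of Cd3g -0.20, of Tcf12 0.01 and of Gfi1 0.21, without emigrants oil 2 that of Ptcra was -0.19, and without emigrants oil 1 that of Tox was 0.01 and of Tbx21 -0.22. Rag1 lay at 9.81 in emigrants oil 2 and at 3.89, 5.10 and 3.75 in the other emigrant arrays, and Myb lay at 5.31 in emigrants TCDD 2 and at 10.00, 9.96 and 10.59 in the others. From oil to TCDD Tbx21 went from 7.01 to 6.46 in number 1 and from 6.36 to 5.81 in number 2. Gfi1 went from 7.04 to 7.09 and from 6.72 to 5.34.

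By limma 0 genes passed over all genes in the emigrants (smallest adjusted p = 1), and 146 had an unadjusted p under 0.05, 67 higher and 79 lower. Single arrays moved these counts: at an unadjusted p under 0.05 there were 791 genes without emigrants TCDD 1 and 325 without emigrants oil 1, where chance gives 620 for independent arrays, and 2 genes (Scin and Ctsg) passed without emigrants TCDD 2. With the Treatment field of emigrants oil 1 there were 512, and 1 gene (Fstl1) passed. The arrays of the groups did not overlap for 24.7% of genes, against 33.3% by chance. Adjusted over the list alone, no AhR target gene passed (smallest adjusted p = 0.0584), and Eomes passed within the list of NK cell markers. That was the only 1 of the 29 lists with such a pass, and the number of lists searched is not adjusted for. With a replicate block within each source, chosen after the data were examined, 749 genes had an unadjusted limma p under 0.05 and 0 passed over all genes.

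**Figure D2:**
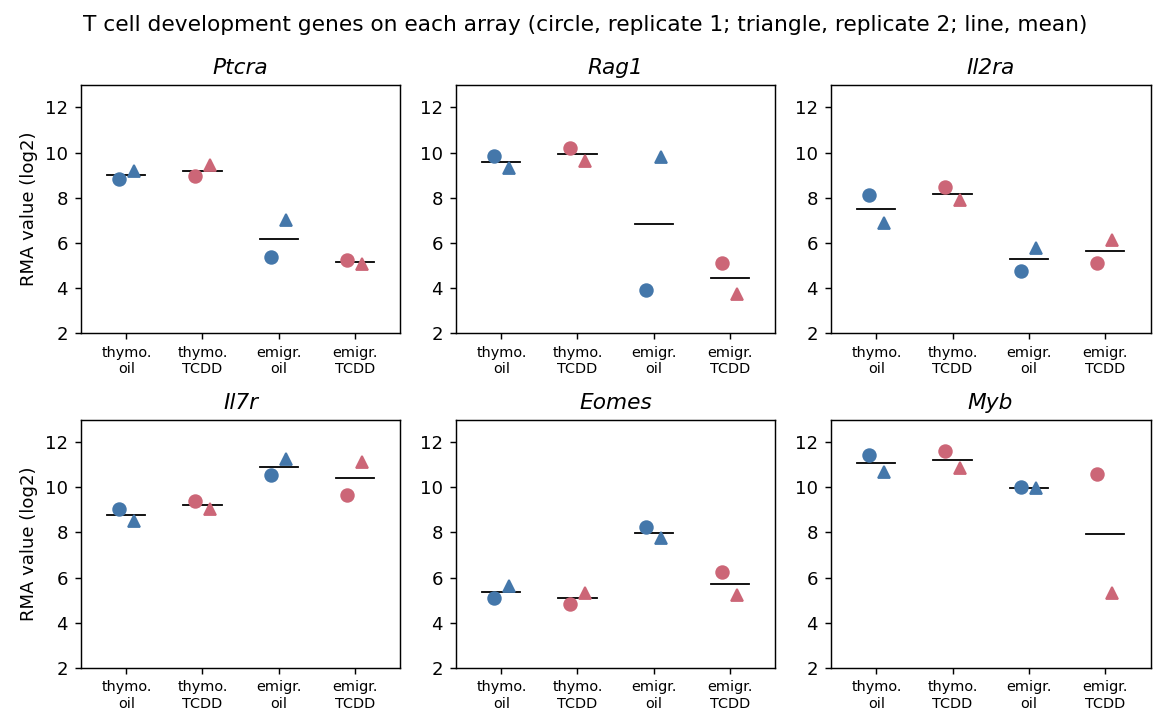
RMA log2 values of 6 genes of T cell development and lymphocyte identity on each of the 8 arrays, by cell source and treatment, with circles for replicate 1, triangles for replicate 2 and lines for the means. Rag1 in oil emigrants and Myb in TCDD emigrants each had 1 array far from the other, at 9.81 against 3.89 and at 5.31 against 10.59.

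The next comparison set emigrants against thymocytes in oil-treated mice. Several genes of the pre-TCR and V(D)J recombination list were lower in the emigrants. Ptcra, the pre-TCR alpha chain, was 7.17-fold lower (log2 difference -2.84, SE 0.51, n = 2 against 2). Il2ra, the IL-2 receptor alpha chain, was 4.67-fold lower and Xrcc6, the Ku70 subunit of DNA end joining, 5.79-fold lower. Rag1, of the same list, lay at 3.89 and 9.81 in the oil emigrants and at 9.85 and 9.33 in the oil thymocytes. Notch1 and Notch3 were 3.75-fold and 2.49-fold lower, with differences of -0.07 and -0.27 for their other probe sets, at mean levels of 5.47 and 5.03. Il7r, the IL-7 receptor, was 4.43-fold higher in the emigrants, and Cd44 had a log2 difference of 0.94. The other genes fixed for naming had differences of 0.21 for Cd4, -0.70 for Cd8a, 0.38 for Ccr9, -1.79 for Cd24a and 0.54 for Ptprc. Single arrays moved some of these: Ptprc was 0.14 without emigrants oil 1, Ccr9 0.20 without emigrants oil 2, Cd44 0.61 and Cd4 -0.12 without thymocytes oil 1, and Cd8a 0.05 without thymocytes oil 2. The other Ccr9 probe sets had larger differences of 1.60 and 0.73, at mean levels of 6.47 and 4.16. The genes with the smallest p on the higher side were Cyp4v3 (1.69), Klf6 (2.13), Ahnak (2.54), Gpcpd1 (1.58) and Cotl1 (2.29), and on the lower side Rgcc (-1.99), Khdc1a (-3.07), Fkbp5 (-2.30) and Ebna1bp2 (-1.35) besides Xrcc6. Khdc1a lay below the array medians in both emigrant arrays. Other probe sets of these genes had smaller differences: 0.26 for Cotl1 at a mean level of 8.66, -0.17 for Ahnak at 5.87, 0.34 for Klf6 at 5.11 and -0.48 for Fkbp5 at 5.69.

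The pre-TCR and V(D)J recombination list fell from thymocytes to emigrants (median -1.56, camera adjusted p = 3.25e-05; adjusted p = 0.199 with an estimated correlation), as did Notch targets (median -1.26, camera adjusted p = 0.000143; adjusted p = 0.199 with an estimated correlation). Cell cycle genes fell (median -0.96, camera adjusted p = 1.32e-09; adjusted p = 0.272 with an estimated correlation), with Aurkb at -1.37, Mcm5 at -1.57 and Ccnb2 at -1.73. Oxidative phosphorylation genes fell (median -0.61, camera adjusted p = 7.10e-06; adjusted p = 0.199 with an estimated correlation), with Atp5b at -1.70, Uqcrc1 at -1.13 and Ndufb5 at -0.69, and ribosomal protein genes fell (median -0.44, camera adjusted p = 0.000115; adjusted p = 0.199 with an estimated correlation), with Rps6 at -0.95, Rpl4 at -0.69 and Rpl8 at -0.96. MHC class II genes, which antigen-presenting cells express, fell (median -1.38, camera adjusted p = 1.88e-05; adjusted p = 0.199 with an estimated correlation), with Cd74 at -1.03, H2-Eb1 at -2.11 and H2-Aa at -1.82, and 5 of the 6 measured members passed when adjusted over the list alone. Without emigrants oil 1 the pre-TCR median was -0.78, and the cell cycle median was -1.47 without emigrants oil 2 and also without thymocytes oil 2, with both calls kept. Without emigrants oil 1 the difference was -0.88 for Aurkb, -0.87 for Mcm5 and -0.56 for Rpl8. With every probe set tested the median was -0.34 for Notch targets and -0.83 for the pre-TCR list, and with the mean of all probe sets -0.79 and -1.02, with the calls kept. B cell markers fell (median -0.14, camera adjusted p = 0.0101; adjusted p = 0.272 with an estimated correlation), with Ms4a1 at -2.45, Ighm at -1.61 (-0.43 for another probe set, at a mean level of 6.59) and Cd79b at -1.31, and the granulocyte list fell (median -1.13, camera adjusted p = 0.0113; adjusted p = 0.603 with an estimated correlation), with S100a9 at -1.93, Cd177 at -0.89 and Elane at -0.38.

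NK cell and cytotoxic markers rose in the emigrants (median 0.63, camera adjusted p = 0.000343; adjusted p = 0.199 with an estimated correlation), and Eomes (2.62), Tbx21 (1.97) and Klrd1 (2.70) passed when adjusted over the list alone. Another Eomes probe set, at a mean level of 4.93, had a difference of 0.62. In all, 12 lists held members that passed in this way. Adhesion genes rose (median 0.38, camera adjusted p = 0.00022; adjusted p = 0.199 with an estimated correlation), with Itgb7 at 1.38, Icam1 at 0.78 and Itgae at 1.56, and genes of thymus egress and migration rose (median 0.38, camera adjusted p = 0.0196; adjusted p = 0.262 with an estimated correlation), with the sphingosine-1-phosphate receptor S1pr4 at 1.37, Ccr2 at 1.74 and Cxcr3 at 1.47. Immediate early genes rose (median 0.61, camera adjusted p = 0.000343; adjusted p = 0.31 with an estimated correlation), with Klf6 and Ier2 (1.07) higher and the member Btg2 at -0.71. Interferon response genes rose (median 0.30, camera adjusted p = 0.00952; adjusted p = 0.272 with an estimated correlation), with Gbp2 at 1.16, Iigp1 at 1.58 and Rsad2 at 1.16. Of the 13 calls, 9 held whichever array was left out. The adjusted p rose to 0.0924 for B cell markers without thymocytes oil 2, at a median of -0.17, to 0.123 and 0.201 for the granulocyte list without emigrants oil 2 and without thymocytes oil 1, to 0.0832 for interferon genes without thymocytes oil 1, and to 0.0956 and 0.089 for egress genes without emigrants oil 1 and without thymocytes oil 1, where the egress medians were 0.22 and 0.23. With the Treatment field of emigrants oil 1 the egress median was 0.22 (adjusted p = 0.0996). Without emigrants oil 1 the adhesion median was 0.18, and the NK median was 0.39 without emigrants oil 2 and 0.37 without thymocytes oil 1. The immediate early median was 0.14 without emigrants oil 2, 0.96 without emigrants oil 1 and 0.98 without thymocytes oil 2. The granulocyte median was -0.76 without emigrants oil 2 and -0.58 without thymocytes oil 1, and the interferon median without thymocytes oil 1 was 0.19. Cxcr3 had a difference of 0.85 without emigrants oil 2. By limma 0 genes passed (smallest adjusted p = 0.0595), and 1186 had an unadjusted p under 0.05, 555 higher and 631 lower (758 in all without emigrants oil 1). The arrays of the groups did not overlap for 39.3% of genes, against 33.3% by chance.

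Under TCDD, emigrants and thymocytes were compared in the same way. Ptcra was 16.4-fold lower in the emigrants (SE 0.51 on the log2 scale, n = 2 against 2). It lay at 5.25 and 5.08 in the TCDD emigrants, not far above their medians of 4.88 and 4.91, so the size of the fold depends on levels near background. Mpzl2 had a log2 difference of -4.30 (SE 0.29, limma adjusted p = 0.0503), with levels of 2.99 and 3.19 in the TCDD emigrants, close to the lowest value of any array (2.54) and not shown to be above background, so no fold is given. Xrcc6 (-2.14), Notch3 (-1.64), Rgcc (-1.49), Notch1 (-2.12), Rag2 (-1.18) and Il2ra (-2.56) were also on the lower side, and Klf6 (2.14), Cyp4v3 (1.40), Pfkp (1.51), Yaf2 (1.29) and Cotl1 (2.21) on the higher side. Il7r had a difference of 1.17, Cd44 of 1.59, Ccr9 of 0.54, Cd24a of -2.72, Cd4 of 0.34, Cd8a of 0.12 and Ptprc of -0.12. Cd24a lay at 10.61 and 5.72 in the TCDD emigrants, and its difference was -0.28 without emigrants TCDD 2. Without that array Il7r had a difference of 0.44 and Ptprc of 0.15, and without thymocytes TCDD 1 Cd44 had 1.01, Ccr9 0.32 and Cd8a -0.93. Mpzl2 has 3 probe sets, of which 1 had a difference of -0.31. Other probe sets had differences of 0.38 for Cotl1 (mean level 8.66), 0.53 for Klf6 (5.11), 0.14 for Yaf2 (5.76), -0.19 for Notch1 (5.47) and -0.27 for Notch3 (5.03).

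Of the lists, 7 fell and 5 rose. The pre-TCR and V(D)J recombination list fell (median -2.01, camera adjusted p = 3.16e-09; adjusted p = 0.096 with an estimated correlation), as did Notch targets (median -0.79, camera adjusted p = 3.70e-07; adjusted p = 0.096 with an estimated correlation) and ribosomal proteins (median -0.49, camera adjusted p = 4.42e-07; adjusted p = 0.096 with an estimated correlation), with Rps6 at -0.87, Rpl4 at -0.91 and Rps4x at -0.49. MHC class II genes fell (median -1.38, camera adjusted p = 4.42e-07; adjusted p = 0.108 with an estimated correlation), with H2-Eb1 at -2.37, H2-DMa at -1.17 and H2-Ab1 at -1.88, and cell cycle genes fell (median -0.92, camera adjusted p = 4.24e-07; adjusted p = 0.387 with an estimated correlation), with Aurkb at -1.23, Ccnb2 at -1.56 and Mcm6 at -1.13. Oxidative phosphorylation genes fell (median -0.47, camera adjusted p = 3.39e-05; adjusted p = 0.286 with an estimated correlation), with Atp5b at -1.56, Atp5pb at -0.81 and Ndufb5 at -0.57, and B cell markers fell (median -0.30, camera adjusted p = 0.0248; adjusted p = 0.385 with an estimated correlation), with Cd79b at -1.89, Ms4a1 at -2.99 and Fcer2a at -0.34. The pre-TCR median was -0.96 without emigrants TCDD 2, the cell cycle median -0.38 without thymocytes TCDD 1 and the Notch median -1.20 without thymocytes TCDD 2, with all these calls kept. Without emigrants TCDD 2 the difference of Mcm6 was -0.59. With every probe set tested the Notch median was -0.49, with the call kept.

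Immediate early genes rose in the TCDD emigrants against TCDD thymocytes (median 0.94, camera adjusted p = 4.24e-07; adjusted p = 0.286 with an estimated correlation), with Klf4 2.84-fold higher and Ier2 at 0.94. Macrophage markers rose (median 0.52, camera adjusted p = 0.0135; adjusted p = 0.422 with an estimated correlation), with Csf1r at 1.65, C1qb at 1.72 and C1qc at 1.27, and erythroid markers rose (median 0.65, camera adjusted p = 0.0115; adjusted p = 0.387 with an estimated correlation), with Car2 at 3.64, Klf1 at 0.52 and Ermap at 1.97. Egress genes rose (median 0.54, camera adjusted p = 0.0201; adjusted p = 0.286 with an estimated correlation), with Ccr2 at 1.60 and S1pr4 at 0.82, and adhesion genes rose (median 0.12, camera adjusted p = 0.0135; adjusted p = 0.315 with an estimated correlation), with Icam1 at 0.99, Itgb7 at 1.20 and Cd44 at 1.59. Ermap lay at 7.87 and 4.74 in the TCDD emigrants, and its difference was 0.41 without emigrants TCDD 1. Globin probe sets with several gene symbols, left out of the list, were not higher in the TCDD emigrants. Alpha globin lay at 12.45 and 7.49 there against 13.06 and 9.33 in TCDD thymocytes, and beta globin at 12.86 and 8.07 against 12.87 and 10.38. Without emigrants TCDD 2 the difference was 1.01 for C1qb and 0.50 for C1qc, and without thymocytes TCDD 1 it was 0.45 for S1pr4. Of the 12 calls, 7 held whichever array was left out. Without emigrants TCDD 1 the adjusted p was 0.46 for erythroid, 0.0809 for B cell, 0.229 for adhesion and 0.176 for egress genes. Without emigrants TCDD 2 it was 0.159 for macrophage markers, without thymocytes TCDD 2 it was 0.131 for erythroid and 0.242 for B cell genes, and without thymocytes TCDD 1 it was 0.0576 for egress genes. The medians moved as well: erythroid to 0.23 without emigrants TCDD 1 and 1.11 without emigrants TCDD 2, macrophage to 0.13 without emigrants TCDD 2, egress to 0.32 without emigrants TCDD 1 and 0.36 without thymocytes TCDD 1, B cell to -0.13 without emigrants TCDD 1, -0.14 without thymocytes TCDD 2 and -0.46 without thymocytes TCDD 1, and adhesion to 0.19 without emigrants TCDD 2 and 0.22 without thymocytes TCDD 1. The adjusted p was 0.0505 for egress genes with the mean of all probe sets of a gene (median 0.42), 0.0537 for B cell markers with only the 4 arrays compared (median -0.30, the same size), and 0.128 for macrophage markers with the Treatment field of emigrants oil 1 (median 0.32). The erythroid median without thymocytes TCDD 2 was 0.54, and that of adhesion genes without emigrants TCDD 1 was 0.15. Adjusted over each list alone, 12 lists held members that passed. By limma 0 genes passed (smallest adjusted p = 0.0503), and 1023 had an unadjusted p under 0.05, 472 higher and 551 lower. Without thymocytes TCDD 1 there were 567 at that level and without emigrants TCDD 2 590, both under the 620 that chance gives for independent arrays. The arrays of the groups did not overlap for 37.6% of genes, against 33.3% by chance. Without emigrants TCDD 1, 10 genes passed, and without emigrants oil 1, or without emigrants oil 2, 3 passed (Mpzl2, Ptcra and Cotl1). In the fit without emigrants TCDD 1, the lone TCDD emigrant array was assumed to vary like the other groups.

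**Figure D3:**
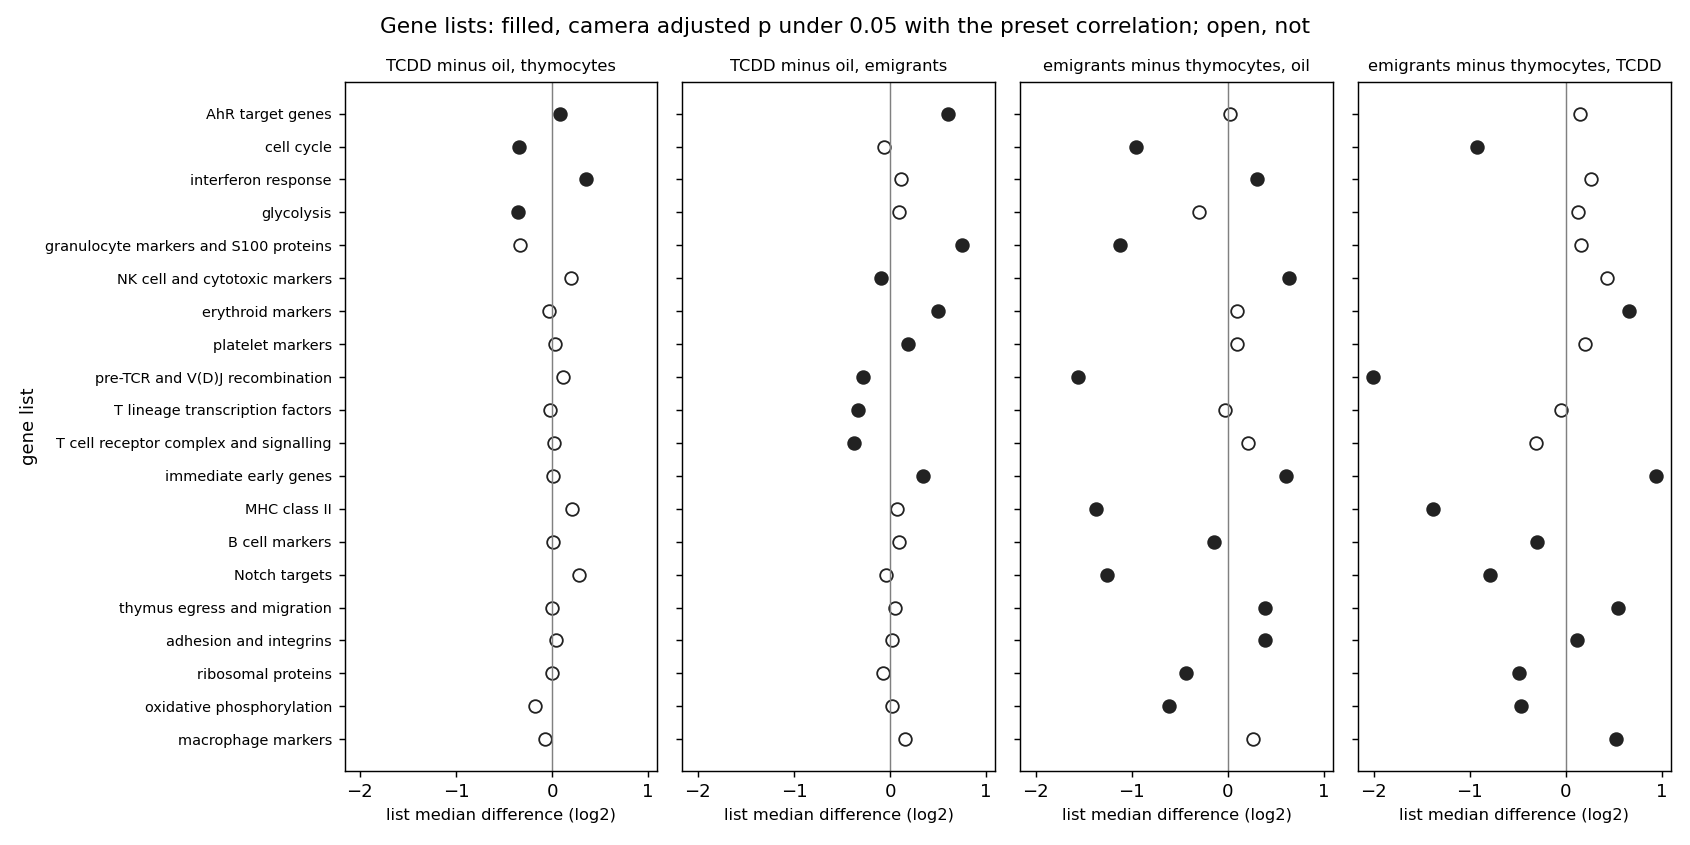
Median log2 difference in the 4 comparisons between groups of the gene lists that passed the camera threshold at the preset correlation in any of them. Filled points mark lists past that threshold in the comparison and open points the others. Lists that passed in none of these comparisons are not drawn. No list passed with an estimated correlation, and the pre-TCR and V(D)J recombination list had medians of -1.56 under oil and -2.01 under TCDD between emigrants and thymocytes.

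Across the 12394 genes, the differences between emigrants and thymocytes under oil and under TCDD had a Pearson r of 0.72 and a Spearman rho of 0.61. The TCDD effects in thymocytes and in emigrants had a Pearson r of 0.02. Both are correlations across genes, which are not independent replicates. The arrays behind the 2 effects of each pair do not overlap, but same-numbered oil and TCDD arrays deviated together within each source (r of 0.76 in thymocytes and 0.50 in emigrants). What they share enters both differences between sources with the same sign, so these are not independent estimates and their r of 0.72 may be raised by it.

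The last comparison tested whether the TCDD effect differed between emigrants and thymocytes. The genes with the smallest p on the negative side, where the effect was lower in emigrants, were Ptbp2 (-1.71, SE 0.27), Mpzl2 (-2.24), Vbp1 (-1.28), Gpcpd1 (-1.23) and Agfg1 (-1.67). On the positive side they were Parvg (1.06), Znhit1 (0.86), Elane (0.93), Ccnd3 (1.08) and Capzb (1.08). Mpzl2 lay below the array medians in all 4 emigrant arrays, so its value and its place among these genes rest on the thymocytes and on levels not shown to be above background. Other probe sets had values of -0.16 for Ptbp2 (mean level 4.92), 0.33 for Parvg (5.14) and -0.07 for Capzb (6.48). The effect on the AhR target list did not pass a test of the difference (median 0.22, camera adjusted p = 0.228). By limma 0 genes passed (smallest adjusted p = 1). At an unadjusted p under 0.05 there were 146 genes, 36 higher and 110 lower, against 792 with a replicate block within each source. There were 519 without emigrants TCDD 1, 302 without thymocytes oil 2 and 241 without thymocytes oil 1, and 254 with the Treatment field of emigrants oil 1, under which 1 gene (Fstl1) passed.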

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

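The tests that weigh explanations in this part were all chosen after the results were seen. The TCDD effect of 5 gene lists differed between emigrants and thymocytes by the camera test of the interaction with a preset correlation, and no list passed with an estimated correlation (smallest adjusted p = 0.566). Each of the 5 calls ended when some single array was left out. The granulocyte list had a median of 0.96 for emigrants minus thymocytes, with Prtn3 at 1.38 and Cd177 at 0.96 (both 0.47 without emigrants TCDD 1), and a median of 0.09 without emigrants TCDD 1 (adjusted p = 0.998) and 0.22 without thymocytes TCDD 2 (adjusted p = 0.107). It was 2.30 without emigrants TCDD 2, 1.67 without thymocytes TCDD 1 and 0.62 without thymocytes oil 1, with the call kept. The glycolysis list had a median of 0.50, with Hk2 at 0.83, Pkm at 0.85 and Pgam1 at 0.59, and a median of 0.27 (adjusted p = 0.101) without emigrants oil 1, while it was 0.82 (adjusted p = 8.41e-07) without emigrants oil 2 and 0.30 (adjusted p = 0.0103) without emigrants TCDD 2. With the Treatment field of emigrants oil 1 in place of the title, its median was 0.12 (adjusted p = 0.464), and the NK cell call ended as well (-0.31, adjusted p = 0.116). The NK cell list had a median of -0.50, with Eomes at -1.98 (-0.52 for another probe set), Klrd1 at -2.05 and Tbx21 at -0.67, and a median of -0.23 (adjusted p = 0.107) without thymocytes TCDD 2 but -0.99 (adjusted p = 0.000217) without thymocytes TCDD 1. The T cell receptor list had a median of -0.39, with Cd3g at -0.56, Cd2 at -1.36 and Ptprc at -0.65, and the interferon list had a median of -0.21, with Mx1 at -0.52, Iigp1 at -0.84 and Rsad2 at -0.61 (0.31 for another probe set). Mx1 lay below the array medians on every array. The T cell receptor call ended without emigrants oil 1 (median -0.16, adjusted p = 0.626), emigrants TCDD 2 (-0.14, 0.612), thymocytes oil 1 (-0.33, 0.0512), thymocytes oil 2 (-0.36, 0.226) and thymocytes TCDD 1 (-0.19, 0.146), and the median was -0.77 (adjusted p = 0.00374) without emigrants TCDD 1. The interferon call ended without emigrants oil 2 (median -0.31, adjusted p = 0.15), emigrants TCDD 1 (-0.47, 0.0778), emigrants TCDD 2 (-0.23, 0.112), thymocytes oil 1 (-0.05, 0.271) and thymocytes TCDD 2 (0.01, 0.353), and the median was -0.40 without thymocytes TCDD 1 and -0.35 without thymocytes oil 2, with the call kept. These last 2 calls also ended with arrays quantile-normalized again (medians -0.42 and -0.14, adjusted p = 0.0686 and 0.0593) and among the brighter genes alone (-0.32 and -0.15, 0.147 and 0.208). The interferon call ended with the mean of all probe sets (-0.15, 0.0672) and with every probe set tested (-0.15, 0.137), and the T cell receptor call with the Treatment field (median 0.03, adjusted p = 0.9).

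For the granulocyte list, a rise in both TCDD emigrant arrays was argued against: emigrants TCDD 1 lay above both oil arrays for 14 of 15 members, and emigrants TCDD 2 for 4, while it lay below both for 7. Leaving out emigrants TCDD 1 took the median of the TCDD effect from 0.75 to -0.17, so myeloid RNA in that array is a candidate explanation. On that array S100a8 lay at 10.61, S100a9 at 8.93 and Camp at 8.86. The thymocyte arrays, with S100a8 between 8.43 and 9.98, carry these genes too, and the series design describes a sort for FITC-positive cells, which would remove unlabelled myeloid cells of the spleen. A TCDD effect on such cells stays open, since 1 array cannot separate it from a difference between samples.

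The conflict in the labels of emigrants oil 1 was set against the data. The mean of Cyp1b1, Scin and Tiparp, the AhR target genes with the smallest p in the thymocyte arrays, was 5.38 on that array, 5.65 in emigrants oil 2 and 8.19 and 7.92 in the TCDD emigrants. These values argue against a wrong title for that array.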

How the results depend on the processing

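The replicate block within each cell source was chosen after seeing the data, and the other alternatives before. Precision is limited by 2 arrays per group, a group left with 1 array is assumed to vary like the other groups, and signal over background was not used here. Where a value changed, the cause was not tested. Among called lists, by the direction of the test, 663 values kept direction and call, 109 kept direction and lost the call and 8 reversed. The list median changed sign in 9 cases, in 3 of them with the test in its former direction: the NK list for TCDD in emigrants with the Treatment field (0.01), the T cell receptor list there without emigrants oil 1 (0.02) and the interferon list in the interaction without thymocytes TCDD 2 (0.01). Without 1 array, 80 of 198 gene values moved by over 1.5 times or turned. Over all settings, values of genes printed kept their sign and stayed uncalled in 3320 cases, gained a call in 25 and reversed in 31. With 0 genes called in the main fit, no call could be lost, so the first count speaks for the sign only. The genes printed are a part of those the naming rule gives, narrowed after the data were examined. Over all 671 gene-by-comparison pairs of the rule, 275 of 11370 values changed sign, 200 of them with 1 array left out and 46 with the Treatment field, at a median size of 0.24 before the change. With quantile normalization repeated, 2 genes (Mpzl2, Klf6) passed between sources under TCDD, Ptprc there was 0.01, and 3 lists passed in the interaction. Among the brighter genes alone 5 lists passed for TCDD in emigrants. With the mean of all probe sets, 1 gene (Il7r) passed between sources under oil, Cd4 there was -0.08, Cd8a under TCDD was -0.12 and Rsad2 in the interaction was 0.01. With trend and robust settings 1 gene (Mpzl2) passed between sources under TCDD. With the Treatment field in place of the title, 1 gene (Fstl1) passed for TCDD in emigrants, 3 between sources under oil, 18 between sources under TCDD and 1 (Fstl1) in the interaction, where 8 lists passed. With that field, for TCDD in emigrants, Tbx21 was 0.07, Tox 0.23, the T lineage list 0.11 and the T cell receptor list 0.19; between sources under TCDD Cd8a was -0.43 and Ptprc 0.07; in the interaction the T cell receptor list was 0.03. With an estimated correlation 0 lists passed in each of the 5 comparisons. Leaving out 1 array gave 0 to 10 genes between sources under TCDD and 0 to 2 for TCDD in emigrants, and 2 to 9 lists for TCDD in thymocytes, 4 to 11 for TCDD in emigrants and 5 to 9 in the interaction. The ranges for TCDD in thymocytes were -0.05 to 0.15 for Aldh3a1, -0.25 to 0.03 for Cyp1a1, -0.51 to 0.33 for Nfe2l2 and -0.12 to 0.28 for Selenbp1. For TCDD in emigrants they were -0.09 to 0.29 for Aldh3a1, -1.54 to 0.21 for Gfi1, -4.67 to 0.61 for Myb, -0.08 to 0.34 for Nfe2l2, -5.38 to 0.54 for Rag1, -2.38 to 2.68 for S100a8, -1.33 to 2.24 for S100a9, -2.34 to 0.01 for Tcf12, -0.68 to 0.01 for Tox and -0.50 to 0.97 for Xdh, and for lists -0.17 to 1.92 (granulocyte), -0.13 to 1.17 (erythroid), -0.45 to -0.05 (pre-TCR) and -0.33 to 0.08 (T lineage). Between sources they were -0.12 to 0.55 for Cd4 and -1.46 to 0.05 for Cd8a under oil, and -0.93 to 1.16 for Cd8a and -0.38 to 0.15 for Ptprc under TCDD. In the interaction the granulocyte list ran from 0.09 to 2.30.

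Same-numbered arrays deviated together within each source, so the oil and TCDD arrays of a source did not vary independently. No label says what a replicate number marks, and 2 arrays per group are too few to settle that from the data. With the number as a replicate block, 0 genes passed in the 5 comparisons (limma, unadjusted p under 0.05 for 270, 229, 1577, 1446 and 248 genes in the order of the report) and 8 lists passed in the interaction. Deviations from the group means correlated at 0.76 between the thymocyte groups, 0.50 between the emigrant groups and -0.10 to 0.11 across sources. With a replicate block within each source, 1 gene, Cyp1b1, passed for TCDD in thymocytes (limma adjusted p = 0.0156, unadjusted p under 0.05 for 790 genes), 0 passed for TCDD in emigrants and in the interaction (unadjusted 749 and 792 genes), and 9 lists passed in the interaction.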

Other observations

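The tests of explanations in this part were chosen after the values were seen. Among the lists not yet described, double-positive thymocyte markers had medians of -0.73 (camera adjusted p = 0.0542) under oil and -0.70 (camera adjusted p = 0.0672) under TCDD between emigrants and thymocytes. They and 8 other lists passed in none of the 5 comparisons. The smallest camera adjusted p was 0.0672 for cytokines and chemokines, 0.0917 for early progenitor genes, 0.0963 for heat shock proteins, 0.111 for thymic epithelium and stroma, 0.353 for apoptosis and 0.635 for gamma-delta genes, each for emigrants against thymocytes under TCDD. It was 0.0683 for dendritic cell markers in the interaction and 0.227 for regulatory T cell genes in the thymocytes under TCDD against oil. The sign of the median and the direction of the test differed in 8 cases, none of them past the threshold: macrophage markers for TCDD in thymocytes (-0.07), oxidative phosphorylation for TCDD in emigrants (0.02), dendritic cell markers (0.02), T lineage factors (-0.03) and gamma-delta genes (-0.04) between sources under oil, regulatory T cell genes (0.07) between sources under TCDD, and egress (0.02) and cytokine genes (0.04) in the interaction.

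Arrays numbered 1 and 2 differed within each cell source in the same genes under oil and TCDD. In thymocytes 231 genes were over 2-fold higher and 165 over 2-fold lower in both number 2 arrays than in their number 1 partners, and in emigrants the counts were 123 and 171. The 18S rRNA 5 prime probe set lay at 7.07 and 7.81 in emigrants oil 1 and TCDD 1 and between 3.95 and 4.29 in the other 6 arrays. Car1 lay at 7.88 and 8.61 in these 2 arrays and between 4.07 and 4.64 in the others. An alpha globin probe set with several gene symbols lay between 11.28 and 13.06 in the number 1 arrays and between 7.13 and 9.33 in the number 2 arrays. In thymocytes the 3 prime minus 5 prime signal of actin was 4.12 and 4.31 in the number 1 arrays against 3.12 and 3.06 in number 2. That of Gapdh was 6.23 and 5.90 against 4.97 and 4.78. In emigrants it was 3.92 and 4.68 against 3.34 and 3.79 for actin, and 4.81 and 4.97 against 4.91 and 5.32 for Gapdh.

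Eif2s3y, a Y-linked gene singled out after its values were seen, lay at 7.12 and 7.46 in emigrants oil 2 and TCDD 2 and between 2.69 and 2.95 in the other 6 arrays, while the labels describe female mice. Only male cells on these arrays are argued against by the Xist probe set with the highest mean, which lay at 10.17 and 9.36 there. The 2 other Xist probe sets were lower on these arrays, at 8.11 and 7.41 against 11.52 and 11.21 in the emigrant arrays numbered 1, and at 4.35 and 4.63 against 7.08 and 6.66. Thymocytes oil 2, with Eif2s3y at 2.80, had similar levels of 8.17 and 4.05. Of the 8 measured Y-linked genes, 2 had a probe set above all other arrays on both, Eif2s3y and Kdm5d. For Kdm5d this was a dim probe set (3.84 and 3.80 against at most 3.49), and its other 2 probe sets, the brightest among them, were not above all other arrays on both. The lower Xist values go with a share of male cells, which could contribute. Besides Eif2s3y and Kdm5d no Y-linked gene was above all other arrays on both. The probe sets of Uty, Zfy2, Sry, Usp9y and Uba1y lay at 4.62 or lower on every array, under the median of 4.86, so they cannot speak for or against male cells. Tspy-ps lay at 5.19 and 5.14 on the 2 arrays and at up to 5.51 on the others. A share of male cells cannot be told apart from another source of signal. The design gives no group that would set a biological explanation beside these, and none was tested.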
